A study of Mus musculus with 2 samples.

How the data were processed

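Total RNA from whole mouse lungs at embryonic day 18 was profiled on 2 Affymetrix arrays, 1 for wildtype lungs and 1 for lungs homozygous for the Nmyc9a allele. Per the labels, RNA was extracted with Trizol and then an RNeasy kit, labelled with biotin and processed with the Affymetrix labelling protocol, and each sample came from pooled lungs. How many lungs entered each pool, their sex, the strain, the scanner software and its scaling are not given in the sources used here. The deposited values are a linear signal intensity per probe set, with 45101 probe sets per array and a lowest value of 0, reached by 1 probe set on the wildtype array and 3 on the array labelled Nmyc9a. The deposited intensity had the same mean on both arrays, 150, once the lowest and highest 2% of probe sets were trimmed. Global scaling to a common target gives such values, but no source used here states that step.

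The 64 control probe sets were set aside, leaving 45037. Signals of the array labelled Nmyc9a were multiplied by 0.977 so that the median log2 ratio over probe sets at or above the floor was 0, a shift of 0.03. The floor was the 40th percentile of the scaled signals, 49.3. Values below the floor were raised to it before log2 ratios were taken, so a ratio against such a value is a bound. For single genes it is printed as at least that fold, or as a log2 ratio given as that value or higher, or that value or lower. Signals printed in the report are after scaling and before the floor, and pairs of signals give the wildtype array first. Across probe sets above the floor, the log2 signals of the arrays had a Pearson correlation of 0.932, and probe sets are not independent replicates.

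Probe sets were named from the platform annotation, and symbols were updated through Entrez identifiers to the RefSeq annotation of GRCm38.p6, which matched 34741 of the 34945 probe sets with 1 symbol. A further 932 probe sets named several genes and were not used for any gene, and 9160 had no listed gene. Each of 18193 genes took its brightest probe set, and 12600 (69.3%) were measured, meaning that the mean signal of the arrays was at or above the floor. Other probe sets of a gene can disagree with the brightest: of 66 higher genes with at least 2 measured probe sets 35 had all of them higher, and of 65 lower genes 43 had all of them lower. Of the genes at least 2-fold apart, 40 higher genes had a wildtype signal below the floor, and 38 lower genes had such a signal on the array labelled Nmyc9a.

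With 1 array per group no test was run, and genes were counted by size, 2-fold for all genes and 1.5-fold for members of gene lists. The groups, the size rules, the floor, the 33 gene lists, the naming rule and all alternatives except those named as chosen after the data were seen were fixed before the data were examined. A list's median log2 ratio was set against 10000 random lists of the same size, matched in 20 bins of mean signal, as a description of these arrays only. Lists with under 5 measured members have values only. Named genes were the Myc family and the 12 highest and 12 lowest genes that met the following conditions. They were at least 2-fold apart, and their brighter array was at or above its 60th percentile. All their measured probe sets had the same sign, and they kept at least 1.5-fold in every scaling set beforehand. Genes with 1 measured probe set, such as Alb and Myh11, meet the sign condition automatically. Clones and predicted genes were counted and not named. From each list the 2 highest and 2 lowest members were named as well. These ranks use values after the floor, so a gene with only a bound has no exact place among them. Further genes named in the closing section were chosen after their values were seen.

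The lists covered the Myc family, distal tip progenitors, type 2 and type 1 alveolar, club, ciliated, neuroendocrine and airway basal cells, endothelium, smooth muscle and pericytes, fibroblasts and matrix, and mesothelium. They also covered macrophages and granulocytes, lymphocytes and thymus, erythroid cells, heart and skeletal muscle, liver, cartilage, nerve and glia, proliferation, ribosome biogenesis, metabolic and chaperone targets of Myc, cytosolic ribosomal proteins and oxidative phosphorylation. The remaining lists were hypoxia and glycolysis, cholesterol and fatty acid synthesis, the p53 response, immediate early and heat shock genes, glucocorticoid response, hedgehog, Fgf, Bmp and Wnt readouts, sex-linked genes, and Hox genes with brown fat.

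The alternatives set beforehand were the values as deposited, quantile normalization and loess on mean signal with a span of 0.3. They included a floor at the 20th or 60th percentile or none, a pseudocount in place of the floor, and the median of a gene's probe sets. Another left out probe sets whose names end in _x_at, _s_at or _a_at, called x, s and a probe sets below. The last were 1.5-fold and 3-fold size rules. Centring and loess on the named genes only were added after the data were seen. The procedure was tested on simulated data made for this comparison in which 200 genes were changed. After the simulation 12828 genes were measured, namely 185 of the changed genes and 12643 unchanged ones. It called 48% of genes changed 2-fold and 89% of those changed 4-fold, and it recovered a simulated scale factor of 1.2 as 1.219. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.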

Results

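RNA was measured on Affymetrix mouse arrays in whole lungs taken at embryonic day 18, shortly before birth. The wildtype group held 1 array and the group homozygous for the Nmyc9a allele held 1 array, each made from pooled lungs. Nmyc9a is a hypomorphic allele of Mycn, the N-Myc transcription factor that the distal lung epithelium needs for growth. The comparison therefore asks which transcripts differ in lungs with reduced Mycn function just before birth. The deposited signals had a median of 66 on the wildtype array and 77.7 on the array labelled Nmyc9a, and their largest values were 9738 and 10442. With 1 array per group, no difference given here has a replicate check and none carries a p-value. The number of arrays limits the precision, and a pool of lungs shows nothing of the spread between animals. The only error in the data is the disagreement between probe sets of the same gene, a pooled SD of 0.40 on the log2 scale (1.32-fold) over 5671 genes.

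Mycn signal was not lower on the array labelled Nmyc9a. Its brightest probe set read 66.3 on the wildtype array and 84.8 on the array labelled Nmyc9a, a log2 ratio of 0.36. A second measured probe set read 51.1 and 85.4, a log2 ratio of 0.74. The remaining Mycn probe set lay below the signal floor of 49.3 on both arrays. Where these probes lie relative to the altered part of the gene is not known here, so their signals neither support nor contradict the label. The wildtype signals of 66.3 and 51.1 also lay close to the floor, so a decrease could hardly have shown. The ratio of 0.36 was smaller than the SD of 0.40 between probe sets, and 0.74 was larger. Every direction below rests on a label that the Mycn signal could not check. The array is called the array labelled Nmyc9a throughout. Among the 12 measured genes of the Myc family and its partners, Mxd4 was over 1.5-fold higher (256 and 410) and no gene was 1.5-fold lower. Mnt, like Mxd4 a repressor of Myc-driven transcription, had a log2 ratio of 0.52, while Mlx stood at -0.37 and Mxd1 at -0.46. The median of this list was 0.05, inside the range of random lists, and -0.06 with the floor at the 60th percentile.

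Genes of cell division were lower together on the array labelled Nmyc9a. Transcripts of oxidative phosphorylation, of metabolic and chaperone targets of Myc, of ribosome biogenesis and of mesothelium were also lower as lists, by smaller amounts. Liver and skeletal muscle transcripts were higher, and surfactant-producing type 2 and endothelial markers lay slightly higher than genes of like signal. Of 12600 measured genes, 163 (1.29%) were at least 2-fold higher and 174 (1.38%) at least 2-fold lower on the array labelled Nmyc9a, so 48.4% of the 337 were higher. That split moved with the scaling: quantile normalization gave 136 higher and 225 lower (37.7% higher), and centring on the named genes, chosen after the data were seen, gave 224 and 114 (66.3% higher). In simulated arrays with probe set noise of the same size, 149 of 12643 unchanged genes (1.18%) passed the 2-fold rule by noise alone. That count is not split by direction, so its counterpart is the 337 of 12600 and not either side alone. The simulated noise covers probe behaviour and leaves out differences between animals or arrays. Of 31 gene lists with at least 5 measured members, 5 had a median log2 ratio below the middle 95% of 10000 random lists matched on signal, 4 above it and 22 inside it. The median measured gene itself stood at -0.09, and the random ranges carry that offset. At 1.5-fold, the size used for list members, 796 (6.32%) of all 12600 measured genes were higher and 1224 (9.71%) lower. The list counts below stand against that background.

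Among the named higher genes, Cfap61, a cilia and flagella associated gene, read 71 and 686 (9.66-fold higher). Kcnq5, a potassium channel gene, was at least 8.25-fold higher, with a wildtype signal of 22.6 below the floor. Non-coding RNAs stood among the 12 highest named genes: Snhg11 was 5.46-fold higher, Fendrr 3.54-fold, and Neat1, the scaffold of nuclear paraspeckles, 3.18-fold at 223 and 707. Alb, serum albumin, read 140 and 558 and Afp, alpha-fetoprotein, was 3.88-fold higher, while Acta1, skeletal muscle actin, was at least 4.45-fold higher. Chil3, a chitinase-like protein of macrophages, was 3.54-fold higher, Csf3r, the receptor for granulocyte colony-stimulating factor, at least 3.41-fold, Krt4 at least 3.30-fold and Taf15, an RNA-binding protein, 3.06-fold.

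The lower end held several genes of DNA replication and chromosome segregation. Mcm5, a subunit of the replicative helicase, was 3.48-fold lower (324 and 93.1), Sgo2a, which protects centromeric cohesion, 3.44-fold and Spc25, a kinetochore subunit, at least 2.91-fold. Spats2 was at least 4.20-fold lower, the transcription factor gene Sox21 at least 3.82-fold and Zscan10 3.76-fold. Shcbp1 was at least 3.18-fold lower, Nup107, a subunit of the nuclear pore, at least 3.13-fold and Fcsk, a fucose kinase, at least 3.20-fold. Myh11, smooth muscle myosin, read 235 and 77.2, Rusc2 was at least 2.98-fold lower and Ube2g2 2.91-fold. The full naming rule was met by 122 higher genes, of which 19 were clones or predicted genes, and by 152 lower genes, of which 2 were.

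Proliferation genes were lower as a list. Of 35 measured members, 29 were at least 1.5-fold lower, 10 of them at least 2-fold, and none was 1.5-fold higher. The median log2 ratio was -0.88, against -0.25 to 0.06 for the middle 95% of random lists, and none of the 10000 lay lower. Besides Mcm5, Kif23, a motor protein of cytokinesis, read 291 and 114 (2.55-fold lower). Tpx2 at 0.47 and Ccne1 at 0.19 were the only measured members above 0. All measured probe sets were lower for 14 of the 21 members with at least 2 of them. The list stayed below the random range under all 11 alternatives, with 21 to 30 members lower.

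Transcripts for cell growth and energy metabolism were lower to a lesser degree. Among 31 measured metabolic and chaperone targets of Myc, 14 were at least 1.5-fold lower and 1 was higher, with a median of -0.45 (random lists -0.32 to -0.03). Odc1, the rate-limiting enzyme of polyamine synthesis and an established Myc target, was 1.99-fold lower (685 and 345), and the chaperonin subunit Cct5 was 1.93-fold lower. Impdh1 stood at 0.42, and Apex1 stood at 0.64 by its brightest probe set but at -0.52 by the median of its probe sets. Of 32 measured oxidative phosphorylation genes, 14 were lower and none higher, with a median of -0.57 (random lists -0.34 to -0.08). Cycs, cytochrome c, was 2.07-fold lower and Ndufa4 1.86-fold, while Atp5a1 stood at 0.16 and Sdhc at 0.10. Ribosome biogenesis had 4 of 31 members lower, none higher and a median of -0.39 (random lists -0.25 to 0.08). Nhp2, a subunit of the small nucleolar ribonucleoproteins, was 1.77-fold lower and Pes1 1.70-fold, with Utp20 at 0.49 and Nop2 at 0.35. Quantile normalization brought the ribosome biogenesis median inside its random range, at -0.26. Loess fitted on the named genes, chosen after the data were seen, left 5 members of the Myc target list 1.5-fold lower and 2 higher. For oxidative phosphorylation it left 5 lower and none higher. Of 24 cytosolic ribosomal protein genes, 1 was higher and none lower. Their median of -0.24 lay inside the random range and was above 0 after loess (0.01). The higher gene was Rpl12 at 0.71, from signals near the floor (54.7 and 89.4), with Rps9 at -0.04, Rpl27 at -0.46 and Rpl8 at -0.49.

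**Figure D1:**
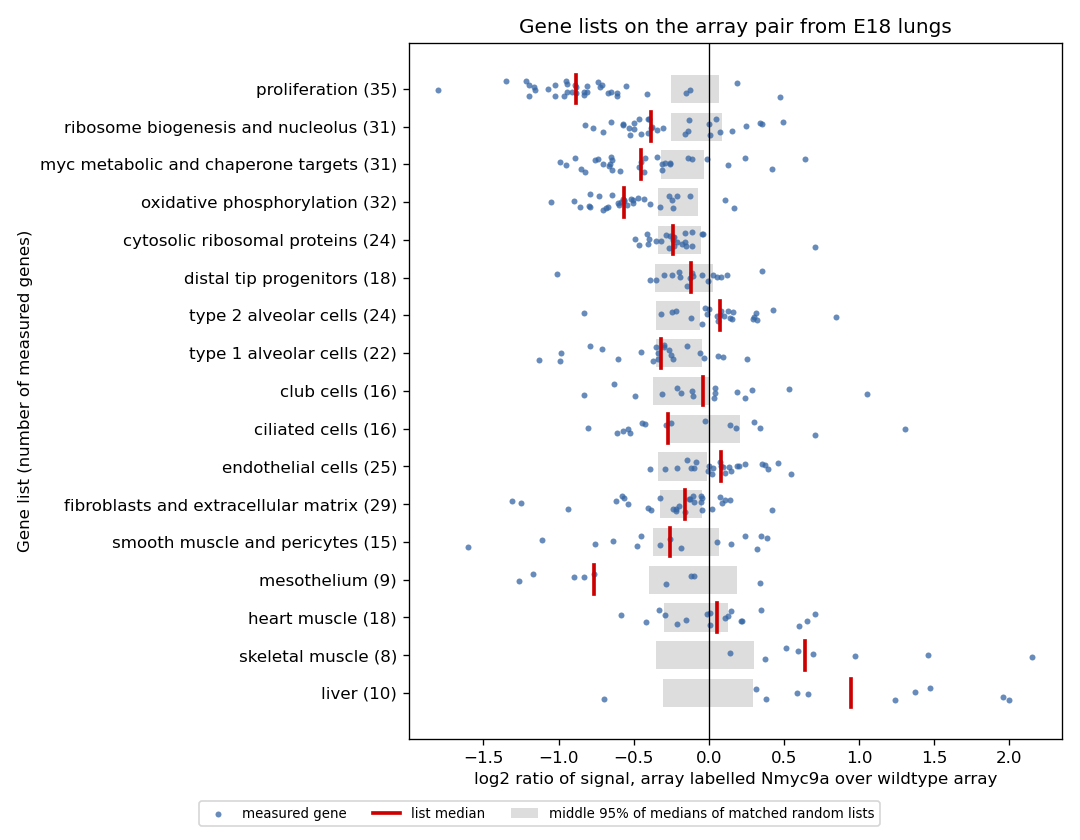
Each blue point is the log2 ratio of signal (array labelled Nmyc9a over wildtype array, horizontal axis) of 1 measured gene, arranged by gene list on the vertical axis with the number of measured genes in brackets. Red bars mark list medians and grey bands the middle 95% of medians of 10000 matched random lists. The proliferation median of -0.88 lies far left of its band and the liver median of 0.95 far right of its own.

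Among epithelial lists of the distal lung, type 2 alveolar genes lay slightly above their random range, and type 1 and distal tip genes lay inside theirs. Of 24 measured type 2 alveolar genes, 1 was at least 1.5-fold higher and 1 lower. Their median of 0.07 lay above the range of random lists matched in bins of signal (-0.35 to -0.06). Chia1 was 1.80-fold higher and Rab27a stood at 0.42, while Sftpd, surfactant protein D, was 1.77-fold lower (4595 and 2589) and Ctsh stood at -0.32. Type 2 medians reached 0.33 after loess. Of 22 type 1 alveolar genes, markers of the flat gas-exchange cells, 6 were lower and none higher, with a median of -0.32 inside the random range of -0.35 to -0.05. That median was -0.09 after loess, inside its random range. After quantile normalization it was -0.1667, at the lower edge of its range (-0.167 to 0.124). Of the 22 genes, 19 stood below 0. Igfbp2 was 2.19-fold lower and S100a6 1.99-fold, with Vegfa at 0.26 and Akap5 at 0.10. Of 18 distal tip progenitor genes, 1 was lower and none higher, with a median of -0.12 that was above 0 after quantile normalization or loess. Foxp2, an epithelial repressor, was 2.02-fold lower (667 and 331), Hmga2 stood at -0.40, Mycn at 0.36 and Cpm at 0.12.

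Airway markers went both ways. Of 16 club cell genes, 1 was higher and 2 were lower, with a median of -0.04 inside the random range, which was above 0 after quantile normalization, loess or centring on the named genes and without a floor. The secretoglobin gene Scgb3a1 was 2.08-fold higher and Scgb1a1, the main club cell secretory protein, stood at 0.54, while Aldh1a1 was 1.55-fold lower. Of 16 ciliated cell genes, 2 were higher and 2 lower, with a median of -0.27 inside the random range. That median became 0.06 without x, s and a probe sets. Ccdc39, needed to assemble ciliary dynein arms, was 2.47-fold higher and Foxj1, the master regulator of motile cilia, 1.63-fold, whereas Dynlrb2 was 1.53-fold lower and Lrrc23 1.75-fold. Among 6 airway basal genes none passed 1.5-fold either way (median -0.16), with Aqp3 at 0.04, Krt5 at 0.01, Pdpn at -0.45 and Krt15 at -0.51. Only 3 neuroendocrine genes were measured, with Syt1 at 0.23, Syp at -0.07 and Ddc at -0.47.

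Of 9 measured mesothelium genes, markers in whole-lung RNA of the lining of the lung surface, 5 were lower and none higher. The median of -0.76 lay below the random range of -0.40 to 0.19, and stood at -0.48 without x, s and a probe sets. Aldh1a2, which makes retinoic acid, was 2.40-fold lower (355 and 148) and Krt19, a keratin that airway epithelium also expresses, was 2.25-fold lower, with Muc16 at 0.34 or higher and Bnc1 at -0.10. None of 25 endothelial genes passed 1.5-fold either way, yet their median of 0.08 lay above the random range of -0.34 to -0.01 and reached 0.27 with loess fitted on the named genes. Flt1, a receptor for vascular endothelial growth factor, stood at 0.55, Vwf at 0.46, Icam2 at -0.29 and Emcn at -0.39.

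Stromal lists lay inside their random ranges, with single genes well apart. Of 29 fibroblast and matrix genes, 4 were lower and none higher (median -0.16, but 0.04 after loess). The proteoglycan gene Vcan was 2.48-fold lower and Tgfbi 2.38-fold, with Fn1 at 0.42 and Col1a1 at 0.14. Of 15 smooth muscle and pericyte genes, 4 were lower and none higher (median -0.26, but -0.02 without x, s and a probe sets). The lowest were Myh11 and the pericyte marker Rgs5, 2.16-fold lower, against Des at 0.39 and Pdgfrb at 0.34. Cartilage genes had none of 8 past 1.5-fold (median -0.10, but 0.26 with the floor at the 60th percentile and -0.30 after quantile normalization), with Acan at 0.48, Col9a1 at 0.26, Hapln1 at -0.44 and Matn3 at -0.57. Nerve and glia also had none of 8 (median 0.10, but -0.27 without a floor), with Ednrb at 0.39, Prph at 0.24, Stmn2 at -0.35 and Gap43 at -0.40. The Hox and brown fat list had 1 of 5 lower, Hoxa5 at 1.51-fold (median -0.10, but 0.16 without a floor), with Cox7a1 at 0.25, Ppargc1a at 0.07 and Fabp4 at -0.49.

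Liver and skeletal muscle transcripts were higher, while heart muscle transcripts lay inside their random range. Of 10 measured liver genes, 7 were at least 1.5-fold higher and 1, the retinol carrier gene Rbp4, was 1.62-fold lower. The liver median of 0.95 lay above all 10000 random lists (-0.30 to 0.30). Besides Alb, Afp read 63.9 and 248, and Hpx, below the floor on the wildtype array, stood at 0.32 or higher. Only 5 of the 14 liver genes on the array reached the floor on the wildtype array, and without a floor the median was 1.38. Of 8 measured skeletal muscle genes, 5 were higher and none lower, with a median of 0.64 (random lists -0.35 to 0.30). Mylpf, a fast-fibre myosin light chain, was 2.74-fold higher (53.6 and 147), while Casq1 stood at 0.37 and Myod1 at 0.14. Of 18 heart muscle genes, 3 were higher and none lower, with a median of 0.06 inside the random range, which was below 0 after quantile normalization. Ryr2 was 1.63-fold higher and Myh6 1.57-fold, while Myl4 stood at -0.42 and Tnni3 at -0.58.

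Blood cell lists lay inside their random ranges. Of 21 macrophage and granulocyte genes, 1 was higher and 5 were lower (median -0.27), with Chil3 higher, Fcgr3 at 0.18, and the neutrophil genes Lcn2 and S100a9 at 1.99-fold and 1.89-fold lower. Of 11 erythroid genes, 2 were lower and none higher (median -0.24). Trim10 was 2.54-fold lower and Slc4a1, the red cell anion exchanger, 1.71-fold, while Hbb-y stood at 0.10 and Rhd at 0.07. The 4 probe sets shared by adult haemoglobin genes had log2 ratios from 0.07 to 0.16. One of them held the largest deposited signal of each array, 9738 and 10442. Whether signals that bright still follow the amount of RNA was not tested. Of 5 lymphocyte and thymus genes, Themis was 1.63-fold higher and none was lower (median 0.23), with Cd8a at 0.31, Ptcra at 0.04 and Thy1 at -0.27. Of the sex-linked genes, Xist read 3976 and 4278, Uty read 84 and 140 (1.67-fold higher), Eif2s3y 63.8 and 73.8, and Kdm5d 91.1 and 86.4.

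Signalling and stress lists also lay inside their random ranges. Of 24 hypoxia and glycolysis genes, 2 were lower and none higher (median -0.31), namely Higd1a at 1.59-fold and Pgk1 at 1.55-fold, with Vegfa at 0.26 and Car9 at 0.22. Of 26 genes of cholesterol and fatty acid synthesis, 4 were lower and none higher (median -0.15). Among these Idi1 was 2.29-fold lower and Msmo1 2.06-fold, both enzymes of sterol synthesis, while Mvk stood at 0.54 and Scd1 at 0.31. Of 17 genes of the p53 response, 1 was higher and 2 were lower (median -0.11). Btg2 stood at 0.59, Sesn2 at 0.42 and Plk2 at -0.65. Mdm2 stood at -0.67 by its brightest probe set but at 0.69 without x, s and a probe sets. Immediate early and heat shock genes had 1 of 20 higher and 3 lower (median -0.15), with Egr3 1.70-fold higher, Klf2 at 0.48, Dusp1 1.66-fold lower and Hsp90aa1 1.71-fold lower. Glucocorticoid response genes had 3 of 18 lower and none higher (median -0.17, but at 0 with loess fitted on the named genes), among them Dusp1 and Lcn2, with Zbtb16 at 0.44 and Errfi1 at 0.11. None of 21 readout genes of the hedgehog, Fgf, Bmp and Wnt pathways passed 1.5-fold (median -0.20, but above 0 after quantile normalization or loess), with Gli1 at 0.53, Nkd1 at 0.38, Id1 at -0.45 and Gli2 at -0.57.

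Control probe sets differed slightly between the arrays. The ratio of 3' to 5' signal was 0.770 on the wildtype array and 0.683 on the array labelled Nmyc9a for Gapdh, and 1.177 and 1.202 for Actb. Probe sets with no listed gene, which enter no gene count or list, were higher on the array labelled Nmyc9a than named ones: 791 of 4143 measured were at least 2-fold higher and 16 lower, with a median log2 ratio of 0.48.

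**Figure D2:**
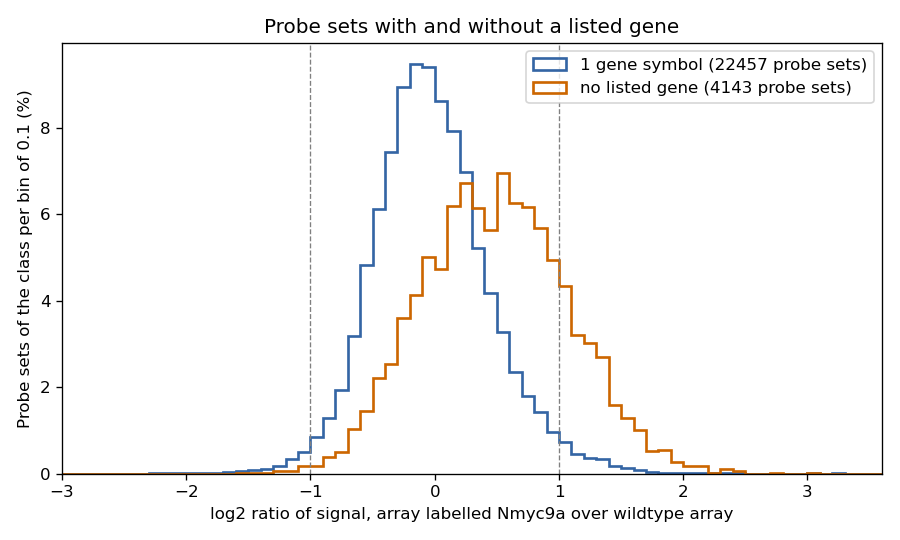
Distribution of log2 ratios of signal (array labelled Nmyc9a over wildtype array, horizontal axis) of measured probe sets with 1 gene symbol (22457, blue) and with no listed gene (4143, orange), as the percent of each class per bin (vertical axis). Dashed lines mark 2-fold; 19.1% of probe sets with no listed gene lie beyond the right line, against 2.39% of those with 1 symbol.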

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

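The tests of explanations for the proliferation, liver and skeletal muscle genes were chosen after those results were seen. The loess and the gene lists they use had been fixed before. The tests on probe sets without a listed gene were also written after their higher signal was seen, but before the values of the tests were read. Probe sets with no listed gene, which enter no gene count or list of the report, stood out for their signal on the array labelled Nmyc9a. Of 4143 measured ones, 791 (19.1%) were at least 2-fold higher and 16 lower, with a median log2 ratio of 0.48. Among 22457 measured probe sets with 1 symbol, 536 were higher and 306 lower, with a median of -0.05. The spike-in controls added at hybridisation also stood out. All 18 of their probe sets were higher on the array labelled Nmyc9a after scaling, by a median of 1.123 times (range 1.03 to 1.445). Several of these probe sets read the same spiked transcript, so they are not 18 separate controls.

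A trend of the ratio with signal is argued against as the whole cause of the excess of unnamed probe sets, since 683 were still higher and 20 lower after loess. A larger share of nuclear or unspliced RNA is one candidate explanation. A list of 21 measured nuclear and non-coding RNAs had a median of 0.24 against -0.32 to 0.06 for matched random lists. Among them Meg3 was 2.40-fold and Kcnq1ot1 2.16-fold higher, while Gas5 stood at -0.47 and Snhg3 at -0.47 or lower. Neat1 and Xist were left out because their values had been seen. Higher non-coding RNAs were part of the pattern to be explained, so this list is not an independent test of it. Extended transcripts read by the dimmer probe sets of named genes would put the dimmest above the brightest in over 60% of genes. After loess it was 49.3% of 5659 genes, which are not independent replicates (95% Wilson interval 48.0 to 50.6). Loess on mean signal itself levels dim and bright probe sets, so that test could hardly have come out otherwise. It also did not reach the unnamed probe sets themselves, and the explanation stays open. Whether such RNA came from handling or from the lungs was not tested.

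For the lower proliferation genes, a trend with signal is argued against by a list median of -0.84 after loess (random lists -0.24 to 0.07). Dilution of mature messenger RNA by a common factor cannot set 1 list apart from named genes of like signal, by the construction of the comparison, so centring on the named genes (-0.79) does not test it, and uneven dilution was not tested. Older lungs in the pool labelled Nmyc9a may also have fewer dividing cells and would raise both alveolar lists. They stay open, since the type 2 median of 0.07 lay above its random range while the type 1 median of -0.32 (-0.09 after loess) lay inside its own under all 11 alternatives. The type 1 list leaned lower and not higher, with 19 of 22 genes below 0. After quantile normalization its median lay at the lower edge of the range. Reduced Mycn function is the biological explanation that the design names. It remains a hypothesis that 1 array per group leaves untested. The Mycn signal, close to the floor on the wildtype array, does not test it either.

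For the liver and skeletal muscle genes, RNA of those tissues taken with the lungs is a candidate explanation. After loess, 13 of 14 liver genes on the array had a higher signal (random lists 2 to 9) and 14 of 16 skeletal muscle genes did (random lists 3 to 11). The abundant liver transcripts Alb, Afp and Ttr read 558, 248 and 137 on the array labelled Nmyc9a, against 140, 63.9 and 35.1. Wildtype lung itself reached the floor for 5 of the 14 and 7 of the 16. The counts after loess include the genes that showed the pattern, so they cannot tell such tissue from a change of these genes within the lung. Such a change was not tested.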

How the results depend on the processing

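Centring and loess on the named genes were chosen after the data were seen, and the other alternatives were set beforehand. Mycn kept a log2 ratio above 0 in each alternative that measured it (0.16 to 0.55). All 9 lists outside their random range stayed on their side wherever they had at least 5 members, except ribosome biogenesis under quantile normalization. Liver and skeletal muscle had 4 members at the 60th percentile floor. Counts of genes 2-fold higher and lower became 565 and 452 with the floor at the 20th percentile, 72 and 86 at the 60th, 1210 and 947 without one and 65 and 55 with a pseudocount, and 114 were lower when centred on the named genes. Size rules of 1.5-fold and 3-fold gave 796 and 1224, and 19 and 11, genes by construction. Under quantile normalization, loess, centring and loess on the named genes, in that order, list medians became 0.24, 0.33, 0.17 and 0.26 for type 2 alveolar cells. In the same order they were 0.21, 0.23, 0.17 and 0.27 for endothelium, -0.26, -0.27, -0.30 and -0.26 for ribosome biogenesis, -0.34, -0.30, -0.36 and -0.26 for Myc targets and -0.35, -0.36, -0.48 and -0.35 for oxidative phosphorylation. Proliferation stood at -0.79 and -0.75 under the last pair, and liver at 1.15 after loess. With a pseudocount the medians were -0.71 for proliferation, -0.30 for ribosome biogenesis, -0.59 for mesothelium and 0.78 for liver. Mesothelium stood at -0.53 with the floor at the 20th percentile and -0.53 without a floor, and at -0.48 without x, s and a probe sets. Without a floor skeletal muscle stood at 0.87 and liver at 1.38, and liver at 1.25 and 1.12 with the floor at the 20th and 60th percentiles. Of the 22 lists inside their random range, 10 kept the sign of their median under all alternatives and 12 did not, and 55 of their 242 medians moved by more than the SD of random lists. Of 1606 values for 151 named genes under the alternatives, 1533 moved by less than the SD between probe sets and 69 by more, and 4 reversed. Apex1 turned from 0.64 to -0.52 both with the median of its probe sets and without x, s and a probe sets. Mdm2 turned from -0.67 to 0.04047 and 0.69 in turn. Beyond the size rules, the cause was not tested. Low signal is a limit, since values below the floor give only bounds. No paired analysis was possible because each group has 1 array.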

Other observations

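The lists of splicing factors and of circadian clock genes, and their comparison with random lists, were chosen after the data were seen, while the test on the neighbours of Mycn was written before their values were read. Splicing factors went both ways: 5 of 23 measured genes were at least 1.5-fold higher and 2 lower on the array labelled Nmyc9a, with a median log2 ratio of 0.27 (random lists -0.36 to -0.03). Taf15 and Arglu1, which had been noticed among the highest genes before the list was written, had log2 ratios of 1.61 and 1.32. Both count in the list's median and among its higher genes, so the comparison with random lists is not independent of that choice. Without them the middle member of the list is Srsf6, at 0.09, which was not set against random lists. Srsf3 and Tra2b, which bind exons and steer splice site choice, were 1.89-fold and 1.83-fold lower. Of 15 measured clock genes, 1 was higher, Per3 at 2.56-fold, and the list median of 0.14 lay inside the random range of -0.31 to 0.18. The only measured probe set of a mitochondrially encoded gene, ND5, stood at -0.07, beside the lower signals of nuclear-encoded oxidative phosphorylation genes.

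DNA of another strain kept around the targeted allele could shift signals of genes next to Mycn. The 31 measured genes among the 20 annotated on each side had a median absolute log2 ratio of 0.39, against 0.16 to 0.45 for the middle 95% of 1890 random runs of neighbouring genes. With 92.1% of random runs below it, the value lay inside that range and leaves the explanation open. Of these neighbours Odc1 stood at -0.99, Ddx1 at -0.70, Greb1 at -0.72 or lower and Atp6v1c2 at 1.02.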
